A study of Rattus norvegicus with 18 samples.

How the data were processed

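The data were the deposited log2 expression values of 41345 probe sets on 18 arrays, with 3 arrays in each of 6 groups: AR10Q, AR112Q and AR112Q-KRKR cells, each with R1881 or vehicle. Per the labels, receptor expression in PC12 cells was induced with doxycycline, the cells were treated with 10 nM R1881 or ethanol for 24 hours, RNA was taken with Trizol, and biotin-labelled cDNA made with an Ambion kit was hybridized on the GeneAtlas system. The authors made the log2 values with RMA, using affy and limma, per the submitters' processing notes. The versions of these tools, the chip definition file and any filters are not given in the sources used here. Values were used as deposited: the array medians lay between 2.925 and 3.045, 12 values were below 0, and 0 sample columns were left unused. No 2 arrays were identical.

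The probe annotation names mouse genes although the cells are from rat. Of all probe sets, 23521 carried 1 gene symbol, 1820 carried several and 16004 carried none. None of the annotated Entrez identifiers (0) occurred in the rat gene table, whereas 15963 of the symbols did. A probe set can therefore read a rat transcript weakly or not at all, and names are those of the array. Among the probe sets, 1395 had the same values on all arrays as at least 1 other, with 802 surplus copies. Without the 3 arrays that stood apart, 68.5% of probe sets had a mean under a log2 value of 4. Ar has no probe set of that name, so the level of the receptor was not analysed here.

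A limma 3.58.1 model with 6 group means was fitted in R 4.3.3 to all probe sets, with 12 residual degrees of freedom and empirical Bayes moderation. The comparisons were the ligand response of each line, the 3 differences between those responses, and the line differences with vehicle between AR112Q and AR10Q and between AR112Q-KRKR and AR112Q cells. P-values were adjusted by the Benjamini-Hochberg method over all 41345 probe sets, and probe sets with an adjusted p under 0.05 were called. Errors after ± are standard errors of the limma fit unless an SD is named. The files carry no pairing of arrays beyond the numbers in the titles, so pairing was not used. Array weights used statmod 1.5.0, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

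The comparisons, the gene lists, the rule for naming genes and the first alternatives were chosen before the data were examined. Gene lists were tested with camera, with its preset correlation of 0.01 between genes, and adjusted over 27 lists in each comparison; each gene was read from its probe set with the highest mean. The lists were written from general knowledge and held 751 entries, of which 674 matched a probe set. They covered androgen response genes of prostate cells, genes shared by steroid receptors, androgen receptor coregulators and the SUMO pathway. Metabolic and stress lists were cholesterol synthesis, fatty acid synthesis, the unfolded protein response, heat shock, the proteasome, lysosome and autophagy, oxidative phosphorylation, hypoxia and glycolysis, oxidative stress, p53 targets and apoptosis, and the interferon response. Growth and neural lists were mitosis, DNA replication, catecholamine and chromaffin genes, neurite outgrowth, immediate early genes, transforming growth factor beta signalling, and ion channels and synaptic genes. Lists for fibroblasts, Schwann cells and satellite glia, adrenal cortex, leukocytes and endothelium stood for other cell types. Where a count of list members is given as adjusted over the list alone, the Benjamini-Hochberg adjustment ran over the members of that list only. The response of genes called in 1 line was compared between the other lines with camera. The mean changes behind those calls came from arrays that the contrast does not use. The residual variance behind them was fitted to all groups, so the set was not chosen independently of the contrast.

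Genes were named by rule. From each comparison came the called probe sets with 1 symbol and the 10 largest rises and 10 largest falls, provided that all 3 arrays of 1 group lay above all 3 of the other in a ligand or vehicle comparison. To these were added the 10 genes with the largest mean change among those called in all lines, and from each list up to 4 members with the smallest p. The other genes printed for the group called in all lines, the genes that describe the 3 arrays standing apart, the probe set without a gene name and the genes at the ends of chromosome stretches were chosen after their values were seen.

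Alternatives were the replicate number as a block, quantile normalization on top of the deposited values, centring of each array, probe sets at or above the median level, probe sets with 1 symbol, a trended and robust prior, array weights, a fit to the compared groups only, a change of at least 1.5-fold, an adjusted p under 0.01, leaving out each array in turn, camera with an estimated correlation, fry, and all probe sets of a list. After the data were seen, a fit without the 3 arrays that stood apart, a fit with an indicator for them, and a fit to distinct probe sets were added. For the order of genes, protein-coding rat genes of assembly GRCr8 with a matching symbol and a mean log2 level of at least 5 on the other 15 arrays were placed, which left 5091 genes, and only their order was used. Marker lists of 21 tissues and cell types, with mammary gland, developing brain and chromaffin cell lists added later, were used to describe the 3 arrays.

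The workflow was tested on simulated data. In the AR10Q ligand comparison, 200 of 41345 probe sets carried planted changes, 50 at each size. The workflow recovered 6% at a log2 change of 0.5, 46% at 1, 82% at 1.5 and 98% at 2, with 9 false calls. For the difference between the AR112Q and AR10Q responses it recovered 0%, 20%, 52% and 58% at the same sizes, with 3 false calls. A planted shift of 0.5 in the proteasome list among 22180 genes was called by camera with 0 other lists of 27. Noise was drawn independently for each gene, so this says nothing about false calls of lists with correlated members. In 5091 simulated genes the correlation between genes 10 places apart was -0.012 with no block and 0.064 with a block of 201 genes shifted by 0.5.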

Results

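Gene expression was measured in PC12 cells, a rat pheochromocytoma line that keeps many properties of adrenal chromaffin cells, induced with doxycycline to express 1 of 3 forms of the androgen receptor. AR10Q carries a short polyglutamine tract, AR112Q carries an expanded tract, the numbers giving the glutamines, and AR112Q-KRKR is the expanded form that cannot be modified by SUMO because its acceptor lysines were exchanged for arginines. A long tract in this receptor is the cause of spinal and bulbar muscular atrophy. Cells received 10 nM R1881, a synthetic androgen, or ethanol vehicle for 24 hours, which gave 6 groups of 3 arrays and 18 arrays in all. The arrays held 41345 probe sets, their median log2 signals lay between 2.925 and 3.045, and the correlation between arrays across probe sets ran from 0.933 to 0.975. The labels do not say that the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. Gene names are those of the array annotation, which names mouse genes, and Ar itself was not analysed here because no probe set carried its name. Differences are log2 differences with the standard error of the limma fit, adjusted p-values are limma or camera values after Benjamini-Hochberg adjustment, and n = 3 arrays per group. In fits without the 3 arrays described next, n = 2 in the groups that lose 1.

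AR10Q vehicle array 1, AR112Q vehicle array 3 and AR112Q-KRKR ligand array 3 stood apart from the other 15. On them 93 probe sets were over 2 log2 units above the mean of the other arrays, 10 of them for mitochondrially encoded genes. The probe set for COX1, a subunit of cytochrome c oxidase, averaged 2.74 ± 0.37 (SD, 15 arrays) elsewhere and read 12.03, 11.21 and 11.98 on these arrays. Csn2, a milk casein, read 9.90, 8.70 and 10.46 against 3.01 ± 0.44, and Fabp7, a fatty acid binding protein of radial glia, read 9.66, 8.28 and 10.85 against 2.49 ± 0.27. Th, the rate-limiting enzyme of catecholamine synthesis, read 10.01, 10.07 and 10.33 against 10.12 ± 0.16. The median change of 9 chromaffin cell genes was -0.014, 0.19 and -0.34 on these arrays, and between -0.21 and 0.235 on each of the others. Values without these 3 arrays are given beside the counts.

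**Figure D1:**
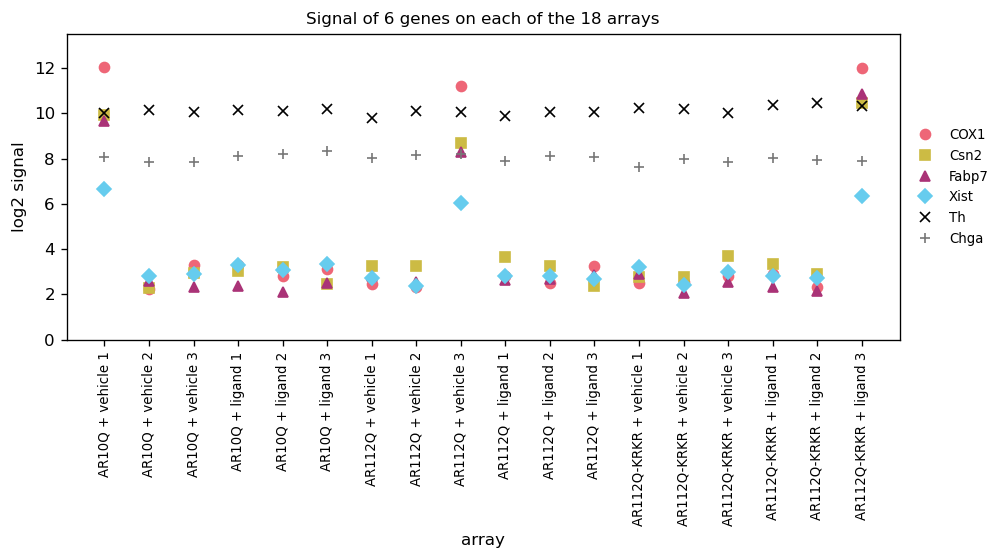
Log2 signal (vertical axis) of 6 genes on each of the 18 arrays (horizontal axis), 1 point per gene and array. COX1 reads 12.03, 11.21 and 11.98 on 3 arrays and averages 2.74 on the other 15, whereas Th averages 10.12 on the other 15 and stays near that value on all.

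The first question was how each receptor changed gene expression when R1881 was added. In AR10Q cells the ligand raised Gadd45g, a growth arrest and DNA damage response gene, 4.04-fold (log2 2.01 ± 0.19, adjusted p = 0.000267). Dop1b rose by 1.87 ± 0.15 (adjusted p = 0.000117), Ctxn1, a neuronal membrane protein gene, by 1.63 ± 0.30, Rasd1, a steroid-induced small GTPase, by 1.45 ± 0.20, and Prex2, an activator of Rac, by 1.43 ± 0.13. The largest falls included Id2, an inhibitor of helix-loop-helix factors, by -1.30 ± 0.21, the Notch target Hey1 by -1.01 ± 0.10, Lmo1 by -0.99 ± 0.14, the homeobox gene Meis1 by -0.95 ± 0.12, and Hand2, a factor of the sympathoadrenal lineage, by -0.77 ± 0.11 (adjusted p = 0.0047). Hoga1, Tlnrd1, Cpne5, Pla2g12a and Adarb1 completed the 10 largest rises, all between 1.21 and 1.43, and Frrs1, Bok, Srgap3, Ano6 and Ppp1r3f completed the 10 largest falls, between -1.03 and -0.81. In all, limma called 80 probe sets, 62 higher and 18 lower. Without the 3 arrays that stood apart it called 67, of which 50 were in both sets; Adarb1 (1.05, adjusted p = 0.126) and Id2 (-1.11, adjusted p = 0.101) were not among them. The count was 48 without AR10Q vehicle array 3, 162 with a trended and robust prior and 0 in a fit to the compared groups only.

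Among the gene lists fixed before the data were examined, the immediate early genes had a mean ligand response of -0.26 in AR10Q cells, with 25 of 29 members below 0 (camera adjusted p = 0.000283, and adjusted p = 0.128 with an estimated correlation). None of them was called over all probe sets and 3 were lower when adjusted over the list alone, among them Klf10 (-0.64 ± 0.13) and Klf4 (-0.92 ± 0.21). The 28 DNA replication genes averaged -0.15 (adjusted p = 0.00303, and adjusted p = 0.128 with an estimated correlation) and the 27 mitosis genes -0.15 (adjusted p = 0.00193, and adjusted p = 0.324 with an estimated correlation). No member was called over all probe sets, and Racgap1, a regulator of cytokinesis, passed when adjusted over the list alone (-0.47 ± 0.12). Cholesterol synthesis genes averaged 0.12 (adjusted p = 0.0295, and adjusted p = 0.416 with an estimated correlation), with Cyp51 at 0.47 ± 0.13 and Dhcr7 at 0.39 ± 0.11 higher when adjusted over the list alone. Their mean was 0.19 without the 3 arrays (adjusted p = 0.000378, and adjusted p = 0.0362 with an estimated correlation). The transforming growth factor beta list averaged -0.20 (adjusted p = 0.0247, and adjusted p = 0.324 with an estimated correlation), but -0.079 with an adjusted p of 0.764 without the 3 arrays; Id2 was its only called member, and not called without the 3 arrays. Single members rose in lists that were not called as a whole: Hspa4l, a chaperone of the Hsp110 family, by 0.91 ± 0.11, Edem1, which acts in the disposal of misfolded glycoproteins, by 0.82 ± 0.11, and Car12, a carbonic anhydrase, by 1.12 ± 0.14. The list of Car12, hypoxia and glycolysis, averaged 0.074 (adjusted p = 0.203) and 0.11 without the 3 arrays, when it was called (adjusted p = 0.031, and adjusted p = 0.177 with an estimated correlation). Fatty acid synthesis likewise went from -0.021 (adjusted p = 0.335) to 0.17 (adjusted p = 0.0103, and adjusted p = 0.085 with an estimated correlation). Of 86 androgen response genes of prostate cells with a probe set, 1 was called over all probe sets and 1 when adjusted over the list alone. Both calls were of Ank, a pyrophosphate transporter (0.60 ± 0.10, and 0.65 with an adjusted p of 0.0673 without the 3 arrays). The list mean was -0.042 (adjusted p = 0.992). Members were not filtered by signal, and some read low, such as Sgk1 at a mean of 2.83 over all arrays. The genes shared by steroid receptors had 1 called member of 25, Rasd1, with 3 higher and 3 lower when adjusted over the list alone, and their mean of 0.0073, median of -0.053 and a test pointing down gave an adjusted p of 0.862.

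In AR112Q cells the ligand raised Fads3, a member of the fatty acid desaturase family, 2.86-fold (1.51 ± 0.13, adjusted p = 0.000524). Ctxn1 rose by 1.71 ± 0.30, Spns2, a sphingosine 1-phosphate transporter, by 1.70 ± 0.26, Dop1b by 1.46 ± 0.15, Gadd45g by 1.42 ± 0.19 and Kctd16, an auxiliary subunit of GABA-B receptors, by 1.20 ± 0.11. Pla2g12a, Adarb1, the kinase gene Wnk2 and 1810055G02Rik rose by 1.29, 1.19, 1.13 and 1.08. The largest falls were Dgkh, a diacylglycerol kinase, at -0.93 ± 0.15, Kcnn3, a calcium-activated potassium channel, at -0.87 ± 0.13, and Meis1 and Hey1, both at -0.87; Bok, Clmn, Ano6, Rhob and Mest fell by between 0.83 and 0.56 on the log2 scale. Limma called 40 probe sets, 29 higher and 11 lower, and 23 without the 3 arrays, of which 18 were in both sets. Adarb1, 1810055G02Rik, Kcnn3, Clmn, Ano6, Rhob and Mest lost their calls there, with adjusted p from 0.06 to 0.17 and log2 values of 1.23, 1.19, -0.87, -0.75, -0.69, -0.68 and -0.55, near those with all arrays. The count was 12 without AR112Q ligand array 2, 106 with a trended and robust prior and 0 in a fit to the compared groups only.

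The DNA replication genes averaged -0.17 with ligand in AR112Q cells, with 23 of 28 below 0 (adjusted p = 4.11e-05, and adjusted p = 0.0157 with an estimated correlation), and Rrm1, which makes deoxynucleotides, read -0.33 ± 0.11. The mitosis list averaged -0.14 (adjusted p = 0.000491, and adjusted p = 0.272 with an estimated correlation). Cholesterol synthesis averaged 0.18 (adjusted p = 0.00501, and adjusted p = 0.272 with an estimated correlation). Hypoxia and glycolysis averaged 0.13 (adjusted p = 0.00501, and adjusted p = 0.272 with an estimated correlation), and Car12 at 0.70 ± 0.14 and Hk2 at 0.58 ± 0.12 were higher when adjusted over the list alone. The transforming growth factor beta list averaged -0.12 (adjusted p = 0.0437, and adjusted p = 0.272 with an estimated correlation) and -0.061 without the 3 arrays, when its adjusted p was 0.244. Called only then were fatty acid synthesis (0.20, adjusted p = 0.00284, and adjusted p = 0.0458 with an estimated correlation), the proteasome (0.13, adjusted p = 0.0115, and adjusted p = 0.403 with an estimated correlation) and the unfolded protein response (0.11, adjusted p = 0.047, and adjusted p = 0.356 with an estimated correlation). No list member was called over all probe sets in AR112Q cells. The androgen response list (mean -0.00051, adjusted p = 0.908) and the genes shared by steroid receptors (mean 0.039, adjusted p = 0.767) were not called. Cebpb (0.63 ± 0.16) and Rasd1 (0.73 ± 0.20) were higher when adjusted over the latter list alone.

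In AR112Q-KRKR cells Gadd45g rose 5.19-fold (2.37 ± 0.19, adjusted p = 2.91e-05). Rhbg, an ammonium transporter of the Rh family, rose by 2.11 ± 0.18 (adjusted p = 3.22e-05), Baiap2, a regulator of the actin cytoskeleton, by 2.08 ± 0.16, and Kcnip3, a calcium-binding partner of potassium channels, by 2.00 ± 0.31. Prex2, Ctxn1, Mfsd2a, Chst1, Nrbp2 and the nuclear receptor gene Ppard rose by between 1.47 and 1.56. Mab21l1, a developmental gene, fell by -1.70 ± 0.14 (adjusted p = 3.22e-05), followed by Fam78a at -1.24, Dgkh at -1.21 and Kcnn3 at -1.14; Tpbgl, Lix1, Kif26b, Clmn and Adamts9 fell by between 1.13 and 1.02 on the log2 scale. Limma called 189 probe sets, 126 higher and 63 lower, and 111 without the 3 arrays, of which 99 were in both sets; Lix1 (-1.08, adjusted p = 0.199) was not. The count was 107 without AR112Q-KRKR vehicle array 2, 344 with a trended and robust prior and 2 in a fit to the compared groups only.

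More lists passed camera in AR112Q-KRKR cells, where the array that stood apart most lies in the ligand group. The 25 genes shared by steroid receptors averaged 0.32 (adjusted p = 2.17e-05, and adjusted p = 0.107 with an estimated correlation; 0.21 without the 3 arrays). Nfkbia, the inhibitor of NF-kappaB, was called over all probe sets (0.98 ± 0.13) and 9 members were higher when adjusted over the list alone, including Cebpb (0.79 ± 0.16), Dusp1 (0.71 ± 0.16) and Klf9 (0.51 ± 0.13). The heat shock list averaged 0.27, with 17 of 19 members above 0 (adjusted p = 0.00023, and adjusted p = 0.0426 with an estimated correlation; 0.18 without the 3 arrays). The unfolded protein response averaged 0.17 (adjusted p = 0.00052, and adjusted p = 0.0501 with an estimated correlation) and the proteasome 0.16 (adjusted p = 8.47e-05, and adjusted p = 0.107 with an estimated correlation). Of their members Edem1 was called (0.90 ± 0.11), and Dnajb1 (0.64 ± 0.14), Bag3 (0.70 ± 0.17) and Psmd8 (0.50 ± 0.13) were higher when adjusted over the list alone. Cholesterol synthesis averaged 0.26 (adjusted p = 0.000124, and adjusted p = 0.107 with an estimated correlation). DNA replication averaged -0.23 with 25 of 28 members below 0 (adjusted p = 2.6e-05, and adjusted p = 0.017 with an estimated correlation). Of these, 4 were lower when adjusted over the list alone, among them Gins1 (-0.60 ± 0.13) and Mcm6 (-0.61 ± 0.15). Ion channel and synaptic genes averaged -0.17 (adjusted p = 0.00359, and adjusted p = 0.159 with an estimated correlation). The sodium channel subunit Scn3b (-0.75 ± 0.11) and the synaptic vesicle calcium sensor Syt1 (-0.71 ± 0.14) fell, and 7 were lower and 1 higher when adjusted over the list alone. Its mean without the 3 arrays was -0.13 with an adjusted p of 0.0576, and Scn3b (-0.71, adjusted p = 0.0537) and Syt1 (-0.78, adjusted p = 0.104) were not called.

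Several further lists passed with all arrays but not without the 3. Fatty acid synthesis went from 0.39 (adjusted p = 0.00128, and adjusted p = 0.164 with an estimated correlation) to 0.15, and the androgen response list from 0.14 (adjusted p = 0.00359, and adjusted p = 0.264 with an estimated correlation) to 0.023. Lysosome and autophagy went from 0.19 (adjusted p = 0.035, and adjusted p = 0.378 with an estimated correlation) to 0.041. Oxidative phosphorylation went from 0.16 (adjusted p = 0.00359, and adjusted p = 0.159 with an estimated correlation) to 0.10, and hypoxia and glycolysis from 0.13 (adjusted p = 0.0142, and adjusted p = 0.172 with an estimated correlation) to 0.10. Oxidative stress went from 0.13 (adjusted p = 0.035, and adjusted p = 0.107 with an estimated correlation) to 0.079, and the interferon response from 0.16 (adjusted p = 0.0417, and adjusted p = 0.34 with an estimated correlation) to 8.64e-05. Called members of these lists were the desaturase Fads2 (0.64 ± 0.13), Vapa (0.61 ± 0.12), the sialidase Neu1 (0.93 ± 0.09), Car12 (0.92 ± 0.14), Hk2 (0.64 ± 0.12) and Gclm (0.74 ± 0.15), a subunit of the enzyme that starts glutathione synthesis. Hand2 (-0.87 ± 0.11), the adhesion molecule gene L1cam (-0.82 ± 0.15), the intermediate filament gene Prph (-0.81 ± 0.17) and Klf10 (-0.80 ± 0.13) fell in lists that did not pass as a whole. Zfp36, which shortens the life of inflammatory mRNAs, rose by 0.90 ± 0.16. Without the 3 arrays Neu1, Car12 and Hand2 kept their calls, and Fads2, Vapa, Hk2, Gclm, L1cam, Prph, Klf10 and Zfp36 did not, with adjusted p from 0.0724 to 0.189 and log2 values from -0.77 to 0.83. Across all comparisons 6 list calls held with an estimated correlation: DNA replication with ligand in AR112Q and in AR112Q-KRKR cells, heat shock with ligand in AR112Q-KRKR cells, and heat shock, oxidative stress and DNA replication between AR112Q and AR10Q cells with vehicle. None of the 6 held with an estimated correlation without the 3 arrays, when their adjusted p-values in that order were 0.0585, 0.0613, 0.15, 0.0696, 0.116 and 0.153. Calls that held only then were cholesterol synthesis in AR10Q (0.0362) and AR112Q cells (0.0441) and immediate early genes in AR10Q cells (0.0362). The others were fatty acid synthesis and hypoxia and glycolysis in AR112Q cells (0.0458 each), and fatty acid synthesis in AR112Q-KRKR against AR112Q cells with vehicle (0.0288).

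**Figure D2:**
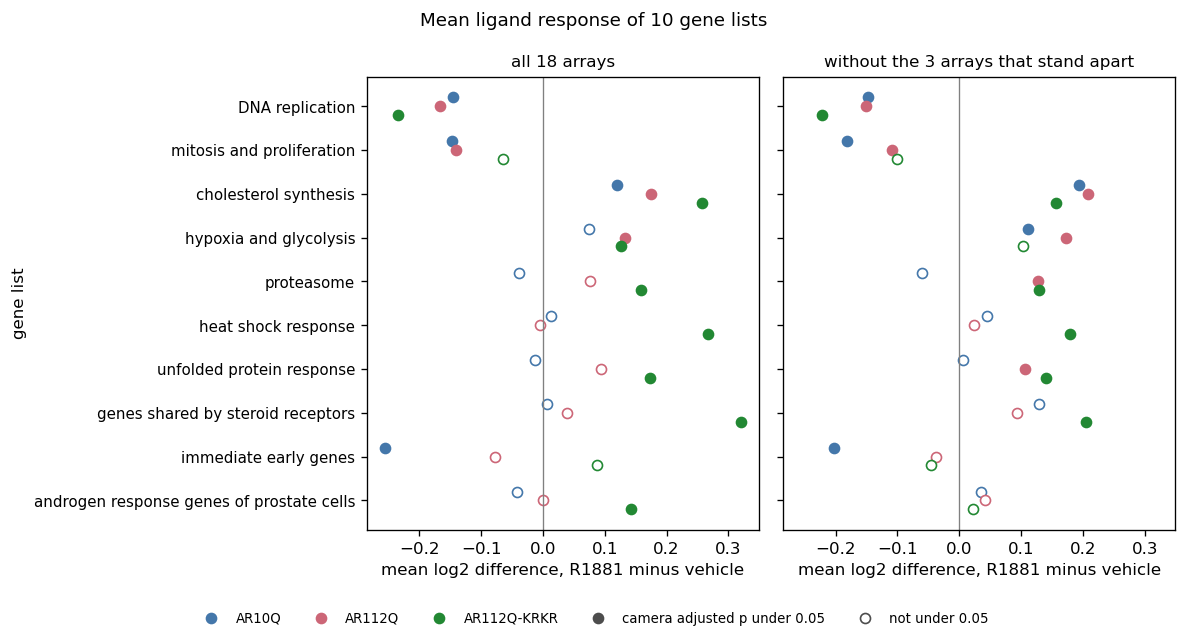
Mean log2 ligand response (horizontal axis) of 10 gene lists (vertical axis) in the 3 lines, with all 18 arrays on the left and without the 3 arrays that stood apart on the right; filled points have a camera adjusted p under 0.05. DNA replication lies below 0 in every line, at -0.15, -0.17 and -0.23 with all arrays, and the androgen response list in AR112Q-KRKR cells moves from 0.14 to 0.023.

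A core of genes responded in all 3 lines. Limma called 24 probe sets in the same direction in every line, 18 higher and 6 lower. Among them were Gadd45g (2.01, 1.42 and 2.37 in AR10Q, AR112Q and AR112Q-KRKR cells), Ctxn1 (1.63, 1.71 and 1.56), Fads3 (1.20, 1.51 and 1.30) and the secreted phospholipase gene Pla2g12a (1.35, 1.29 and 1.36). The RNA editing enzyme gene Adarb1, Ppard, the zinc finger gene Zfand5, Gk5, 1810055G02Rik and Dop1b also rose in each line. The 6 that fell were Bok, Meis1, Clmn, Ano6, Kcnn3 and Hey1, of which Kcnn3 went from -0.71 in AR10Q to -1.14 in AR112Q-KRKR cells. AR10Q and AR112Q cells shared 27 calls where 0.048 would be shared by independent lists, AR10Q and AR112Q-KRKR cells shared 46 against 0.22, and AR112Q and AR112Q-KRKR cells shared 29 against 0.11, with 0 in opposite directions in any pair. Each line had its own vehicle arrays, so these overlaps rest on no shared controls. The calls of all lines did use the same residual variance for each probe set, so the lists were not independent. The expected counts assume independent calls spread evenly over all probe sets, and may be too low. In fits to the compared groups only, few probe sets were called in any line and 0 calls were shared by any pair. Without the 3 arrays the shared counts were 13, 31 and 13, with 10 in all lines, and Adarb1 was called in none.

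**Figure D3:**
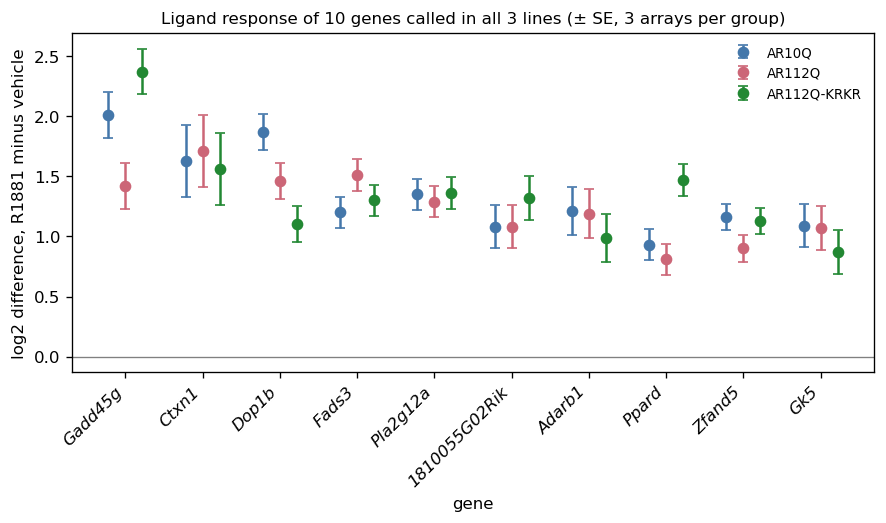
Log2 ligand response (vertical axis, mean ± SE, 3 arrays per group) of the 10 genes with the largest mean change among those called in all 3 lines (horizontal axis), in AR10Q, AR112Q and AR112Q-KRKR cells. The smallest response is 0.81, and Gadd45g runs from 1.42 in AR112Q to 2.37 in AR112Q-KRKR cells.

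The next question was whether the response differed between the lines with the longer and the shorter polyglutamine tract. An effect of the receptor form cannot be told apart from other differences between these lines. No single gene was called for a different ligand response between AR112Q and AR10Q cells. Limma called 0 of 41345 probe sets for the difference between their responses, with 1999 at an unadjusted p under 0.05 where chance alone gives 2067, and a smallest adjusted p of 0.142. The count stayed 0 without the 3 arrays, with 2420 at an unadjusted p under 0.05, and under every other setting tried. Gadd45g responded by 2.01 in AR10Q and 1.42 in AR112Q cells, and Rasd1 by 1.45 and 0.73, a difference of -0.71 ± 0.29 (adjusted p = 0.998). None of the 27 lists passed; immediate early genes had a difference of 0.18 (adjusted p = 0.276) and the proteasome 0.12 (adjusted p = 0.455). The 126 probe sets that rose with ligand in AR112Q-KRKR cells were compared as a set. They were called on mean changes of arrays that this contrast does not use. They were not chosen independently of it, because their calls used a residual variance fitted to all groups. They responded by 0.55 in AR10Q and 0.47 in AR112Q cells, a difference of -0.077 (camera adjusted p = 0.033, and adjusted p = 0.475 with an estimated correlation). For the 88 probe sets called without the 3 arrays it was -0.11 (camera adjusted p = 0.00867 with the preset correlation). The set was called anew under each other setting, and its call was lost with centred arrays (-0.052, adjusted p = 0.148), array weights (-0.047, 0.239), probe sets of 1 symbol (-0.025, 0.331), probe sets at or above the median level (-0.011, 0.39) and a trended and robust prior (-0.017, 0.753). Leaving out single arrays gave adjusted p up to 0.302. The 63 that fell in AR112Q-KRKR cells responded by -0.43 and -0.38 (adjusted p = 0.323). In simulated data a planted difference of 1 log2 unit between these responses was recovered for 20% of probe sets, so differences of that size can be missed here.

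The line whose expanded receptor cannot be modified by SUMO was compared next, as the response of AR112Q-KRKR cells against that of AR112Q cells. Here too, the receptor form cannot be told apart from other differences between the lines. Limma called 0 probe sets, with 2430 at an unadjusted p under 0.05, and a smallest adjusted p of 0.102. It called 1 without the 3 arrays, 7 with a trended and robust prior and 9 among probe sets at or above the median level. The 62 probe sets that rose with ligand in AR10Q cells responded by 0.67 in AR112Q and 0.80 in AR112Q-KRKR cells, a difference of 0.13 (camera adjusted p = 0.00195). For the 49 called without the 3 arrays it was 0.15 (camera adjusted p = 0.00867 with the preset correlation). With all arrays and an estimated correlation the camera adjusted p was 0.324. With the set called anew, its call was also lost with an indicator for the 3 arrays (0.085, adjusted p = 0.132) and with quantile normalization (0.089, adjusted p = 0.0522), and leaving out single arrays took it down to 0.059 and the adjusted p up to 0.302. The 18 that fell in AR10Q cells responded by -0.52 and -0.63 (adjusted p = 0.323). Among the lists, the genes shared by steroid receptors differed by 0.28 (adjusted p = 0.00251, and adjusted p = 0.441 with an estimated correlation). Nfkbia, at 1.16 ± 0.19, was the 1 member that passed when adjusted over the list alone. The heat shock list differed by 0.27 (adjusted p = 0.0133, and adjusted p = 0.321 with an estimated correlation). Androgen response genes differed by 0.14 (adjusted p = 0.0441, and adjusted p = 0.444 with an estimated correlation), the proteasome by 0.082 and ion channel and synaptic genes by -0.19 (both with adjusted p = 0.0441, and adjusted p = 0.441 with an estimated correlation). None of these 5 lists passed without the 3 arrays, when their differences were 0.11, 0.16, -0.019, 0.0011 and -0.13. Plk2, a polo-like kinase, was lower by -1.18 ± 0.26 and Prph by -0.94 ± 0.23 when adjusted over their lists alone. With vehicle Plk2 averaged 6.57 in AR112Q-KRKR and 5.51 in AR112Q cells, and with ligand 5.91 and 6.02. Its levels thus lay further apart with vehicle than with ligand. Without the 3 arrays no member of the neurite outgrowth list, which holds Prph, passed when adjusted over that list alone.

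Set against AR10Q cells, AR112Q-KRKR cells had 4 probe sets with a different response. Rhbg responded by 2.11 in AR112Q-KRKR and -0.23 in AR10Q cells, a difference of 2.34 ± 0.25 (adjusted p = 0.00543, and 0.0136 without the 3 arrays). Nfkbia differed by 1.42 ± 0.19 (adjusted p = 0.0436), with a response of 0.98 ± 0.13 in AR112Q-KRKR and -0.44 ± 0.13 in AR10Q cells. Mab21l1 differed by -1.44 ± 0.20 (adjusted p = 0.0453). With vehicle it read 6.91 to 7.01 in AR112Q-KRKR and 4.7 to 4.99 in AR10Q cells, and with ligand 4.96 to 5.51 and 4.54 to 4.71. Its levels thus lay further apart with vehicle than with ligand. A probe set without a gene name differed by 2.47 ± 0.35 (adjusted p = 0.0453). Nfkbia, Mab21l1 and that probe set differed by 1.42, -1.20 and 2.49 without the 3 arrays, with adjusted p of 0.199, 0.199 and 0.265. The calls comprised 3 higher and 1 lower, with 3333 probe sets at an unadjusted p under 0.05. Lists with a higher response in AR112Q-KRKR cells were the immediate early genes (0.34), the genes shared by steroid receptors (0.31), lysosome and autophagy (0.32), oxidative phosphorylation (0.24), oxidative stress (0.22), the proteasome (0.20), the unfolded protein response (0.19) and the androgen response list (0.18). Ion channel and synaptic genes had a lower one (-0.17). Their adjusted p-values lay between 0.00102 and 0.038 and between 0.159 and 0.372 with an estimated correlation. Of the 8 higher lists 1 passed without the 3 arrays, the proteasome at 0.19 (adjusted p = 0.0136, and adjusted p = 0.527 with an estimated correlation). The androgen response list then turned to -0.012, and lysosome and autophagy read 0.036, the genes shared by steroid receptors 0.076 and immediate early genes 0.16. With all arrays Psmb1 read 0.92 ± 0.33 and Psma2 0.45 ± 0.23, but no proteasome member passed, even when adjusted over the list alone. The response of Psmb1 was -0.79 ± 0.24 in AR10Q cells (adjusted p = 0.345). In AR112Q-KRKR cells Psmb1 averaged 3.99 with vehicle and 4.12 with ligand. The 29 probe sets that rose in AR112Q cells responded by 0.97 in AR10Q and 0.96 in AR112Q-KRKR cells (difference -0.0069, adjusted p = 0.85), and the 11 that fell differed by -0.041 (adjusted p = 0.923). That latter difference turned to 0.43 (adjusted p = 0.0225) for the 9 probe sets called lower without the 3 arrays, which responded by -0.58 in AR10Q and -0.15 in AR112Q-KRKR cells.

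**Figure D4:**
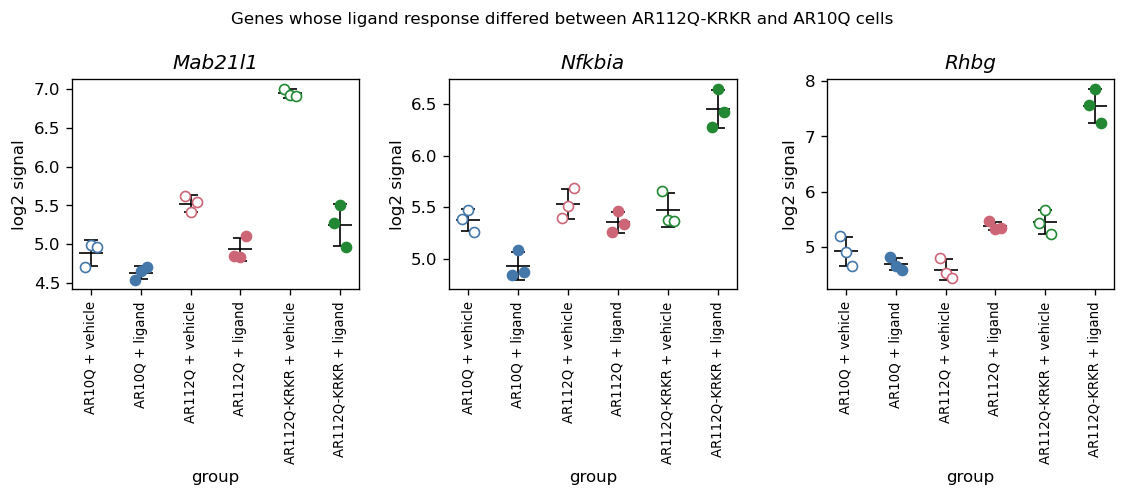
Log2 signal (vertical axis) of Mab21l1, Nfkbia and Rhbg in each of the 6 groups (horizontal axis), 1 point per array with the mean and SD of 3 arrays. The ligand response of each differed between AR112Q-KRKR and AR10Q cells, by -1.44, 1.42 and 2.34.

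The lines also differed before any androgen was added. With vehicle, Ret, the receptor tyrosine kinase for glial cell line-derived neurotrophic factor, was lower in AR112Q than in AR10Q cells by -1.58 ± 0.14 (adjusted p = 0.000188). Also lower were Sdk2, a cell adhesion gene (-1.55 ± 0.12, adjusted p = 7.72e-05), the homeobox gene Hoxa5 (-1.68 ± 0.29), the tachykinin gene Tac2 (-1.41 ± 0.23) and the semaphorin receptor Nrp2 (-1.18 ± 0.20). Gtsf1, a germ cell gene of the piRNA pathway, was higher by 2.21 ± 0.24, Nppc, which encodes C-type natriuretic peptide, by 2.04 ± 0.26, Fgf16 by 1.43 ± 0.21, Dlc1 by 1.27 ± 0.20 and Cdh2, or N-cadherin, by 1.19 ± 0.17. Cabp7, Dlk1, Tdrd9, Chrna7 and the probe set annotated to Olfr484 were higher by between 0.79 and 1.24, and Pkp1, Hsph1, Rfx1, Kctd16 and Emilin1 lower, with values from -1.48 to -0.98. Limma called 43 probe sets, 21 higher and 22 lower, and 15 without the 3 arrays, 9 of them in both sets. Of the genes named here Ret, Sdk2, Gtsf1, Nppc and Cabp7 kept their calls. The others were not called, with adjusted p from 0.0522 to 0.308 and log2 values near those with all arrays, from 0.64 (Olfr484) to 1.42 (Fgf16) for those higher and from -1.90 (Hoxa5) to -0.87 (Emilin1) for those lower. The count was 21 without AR10Q vehicle array 3 and 0 in a fit to the compared groups only.

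Heat shock genes were lower in AR112Q cells with vehicle, at a mean of -0.29 with 16 of 19 below 0 (camera adjusted p = 1.15e-06, and adjusted p = 0.00945 with an estimated correlation; -0.29 without the 3 arrays). The chaperone gene Hsph1 was called (-1.11 ± 0.19; -0.94 with an adjusted p of 0.308 without the 3 arrays), and 7 members were lower when adjusted over the list alone, including Stip1 (-0.65 ± 0.12), Hspd1 (-0.52 ± 0.13) and Fkbp4 (-0.47 ± 0.13). The oxidative stress list averaged -0.18 (adjusted p = 0.000547, and adjusted p = 0.0173 with an estimated correlation), and Sod1 at -0.41 ± 0.13 and Slc7a11 at -0.33 ± 0.10 were lower when adjusted over the list alone. DNA replication averaged -0.14 (adjusted p = 0.00127, and adjusted p = 0.0331 with an estimated correlation). The proteasome averaged -0.19 with 25 of 29 below 0 (adjusted p = 3.58e-05, and adjusted p = 0.107 with an estimated correlation). The mitosis list averaged -0.12 (adjusted p = 0.0149, and adjusted p = 0.457 with an estimated correlation) and oxidative phosphorylation -0.11 (adjusted p = 0.0485, and adjusted p = 0.487 with an estimated correlation; adjusted p = 0.0636 without the 3 arrays). Catecholamine and chromaffin genes averaged 0.12 (adjusted p = 0.0109, and adjusted p = 0.0845 with an estimated correlation), with Hand2, Gata2, Ddc and Slc18a1 higher by 0.44, 0.48, 0.52 and 0.38 when adjusted over the list alone. That list averaged 0.067 with an adjusted p of 0.164 without the 3 arrays.

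Between AR112Q-KRKR and AR112Q cells with vehicle the differences were many. Both vehicle comparisons use the same AR112Q vehicle arrays. The vehicle arrays of a line also enter its ligand response, so a line difference and a ligand response of the same gene are not independent. Dpysl3, a cytoskeletal regulator of growing neurites, was higher in AR112Q-KRKR cells by 2.54 ± 0.15 (5.81-fold, adjusted p = 1.38e-06) on 1 probe set and by 2.05 ± 0.13 on another, and Kif26b by 2.54 ± 0.20. Bmp2, which encodes a bone morphogenetic protein, was higher by 1.97 ± 0.32, the inhibitory Smad6 by 1.88 ± 0.16 and Id2 by 1.36 ± 0.21. The transcription regulators Zfpm2, Atoh8 and Tbx3 were higher by 1.70, 1.49 and 1.48, as were Fam163b and Npw by 1.72 and 1.45. The probe set annotated to the olfactory receptor Olfr1417 was lower by -5.11 ± 0.30 (34.5-fold, adjusted p = 1.38e-06), Nppc by -2.46 ± 0.26, Gtsf1 by -2.25 ± 0.24, C2cd4a by -1.86 ± 0.20, and Ddc, the decarboxylase that makes dopamine, by -1.38 ± 0.14. Dlc1, Rbp4, Itga1, AF357425 and Dlk1 were lower with values from -1.64 to -1.37. Limma called 274 probe sets, 134 higher and 140 lower, and 184 without the 3 arrays, 145 of them in both sets; Npw (1.37, adjusted p = 0.112) was not. The count was 118 without AR112Q-KRKR vehicle array 1, 453 with a trended and robust prior and 23 in a fit to the compared groups only.

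Of the transforming growth factor beta list, 6 of 26 members were called higher and 1 lower in AR112Q-KRKR cells, with Tgfb1 at 0.68 ± 0.11, and 8 higher and 2 lower when adjusted over the list alone. Its mean was 0.23 but its median -0.0074, and camera gave an adjusted p of 0.0602 (0.595 with an estimated correlation). Leaving out the 3 arrays gave a mean of 0.29 and an adjusted p of 0.0277, and 0.133 with an estimated correlation. Heat shock (0.16, adjusted p = 0.0277) and lysosome and autophagy (0.15, adjusted p = 0.00658) were also called only then, both with an adjusted p of 0.194 with an estimated correlation. Among chromaffin genes Gata3 (1.03 ± 0.17) and Isl1 (0.69 ± 0.14) were higher and Ddc lower, with a list mean of -0.00012. In the ion channel and synaptic list Syt1 (1.01 ± 0.14), the purinergic receptor P2rx2 (0.85 ± 0.15) and the sodium channel Scn2a (0.98 ± 0.20) were called higher, with 8 higher and 4 lower when adjusted over the list alone (mean 0.16, adjusted p = 0.0921). Single called members of other lists were the small heat shock protein gene Hspb1 (1.26 ± 0.18), Mertk (1.26 ± 0.18), Plk2 (1.06 ± 0.18), Elovl6 (0.81 ± 0.14), Zfp36 (0.80 ± 0.16) and Prph (0.78 ± 0.17). Without the 3 arrays Tgfb1, Isl1, Scn2a, Elovl6, Zfp36 and Prph lost their calls, with log2 values from 0.60 to 0.94 and adjusted p from 0.0655 to 0.154. The mitosis list averaged -0.14 (adjusted p = 0.00956, and adjusted p = 0.595 with an estimated correlation) and fatty acid synthesis 0.17 (adjusted p = 0.0408, and adjusted p = 0.66 with an estimated correlation; 0.29 without the 3 arrays). These line differences were not spread evenly over the genome. The 247 genes placed on 1 rat chromosome, in the order from Ube3c to Dennd5b, averaged -0.42 ± 0.28 (SD across genes), 229 of them lower in AR112Q-KRKR cells and 53 of them called. The 265 genes of another chromosome, from Gdap1 to Samd11, averaged 0.20 ± 0.21 in AR112Q against AR10Q cells.

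**Figure D5:**
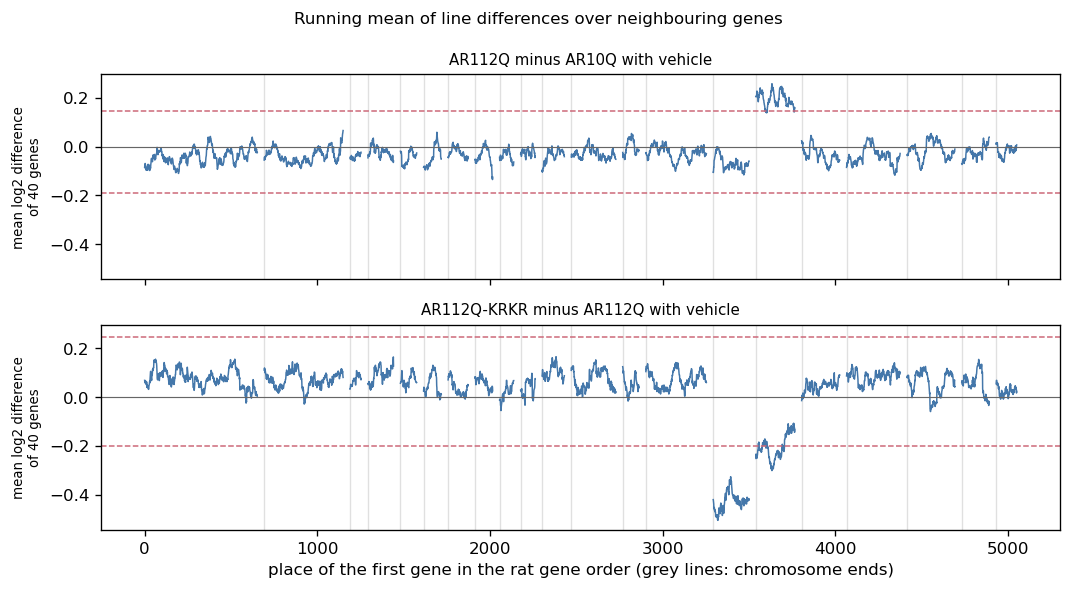
Running mean of the log2 difference with vehicle over 40 neighbouring genes (vertical axis) along the rat gene order (horizontal axis, grey lines at chromosome ends), for AR112Q against AR10Q cells (top) and AR112Q-KRKR against AR112Q cells (bottom). Dashed lines mark the highest and lowest windows of 1000 shuffled orders, 0.145 and -0.189 at the top and 0.247 and -0.2 at the bottom. The genes placed on 1 chromosome average -0.42 at the bottom, where the lowest window is -0.505.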

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

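Among the tests of this part, those of another rat tissue and of the correlation between genes were written after the result was seen, and the other predictions were written before. Each value here drew attention as a difference between lines. In the response of AR112Q-KRKR against AR112Q cells these were the androgen response list (0.142, 59 of 86 members above 0, adjusted p = 0.0441), the genes shared by steroid receptors (0.283, 18 of 25, adjusted p = 0.00251), heat shock (0.272, 15 of 19, adjusted p = 0.0133), the proteasome (0.082, 20 of 29, adjusted p = 0.0441) and ion channel and synaptic genes (-0.185, 11 of 28, adjusted p = 0.0441). With an estimated correlation their adjusted p was 0.444, 0.441, 0.321, 0.441 and 0.441, and without the 3 arrays their values were -0.0192, 0.112, 0.155, 0.0011 and -0.132, none of them called. Against AR10Q cells these were Rhbg (2.34 ± 0.25), Nfkbia (1.42 ± 0.19), a probe set without a gene name (2.47 ± 0.35) and Mab21l1 (-1.44 ± 0.20). Lists with a different response from AR10Q cells were the androgen response list (0.183, 53 of 86 above 0), the genes shared by steroid receptors (0.314, 18 of 25), the unfolded protein response (0.186, 17 of 24), immediate early genes (0.344, 20 of 29), the proteasome (0.197, 26 of 29), lysosome and autophagy (0.32, 19 of 31), oxidative phosphorylation (0.243, 21 of 29), oxidative stress (0.215, 14 of 19), and ion channel and synaptic genes (-0.174, 7 of 28). With an estimated correlation none of these 9 was called, with adjusted p from 0.159 to 0.372. The set of probe sets called higher in AR10Q cells differed by 0.125 between AR112Q-KRKR and AR112Q cells, and the set called higher in AR112Q-KRKR cells by -0.077 between AR112Q and AR10Q cells; with an estimated correlation the adjusted p was 0.324 and 0.475.

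The 3 arrays that stood apart may hold foreign RNA: over 21 lists of tissue markers the one whose median rose most in all 3 was lung, by 0.398 on the lowest array, and for mammary gland and developing brain lists the lowest of the 3 median rises was 0.36 and 0.807, each short of the rise of 1 set beforehand. The lung value met the bound set beforehand against RNA of another tissue, but is not decisive, because milk caseins, outside that list, rose: Csn2 read 9.90, 8.70 and 10.46 against 3.01 ± 0.44 (SD). The median rise of mitochondrially encoded genes was 6.73 on the lowest array (3.15 for ND6 there), which speaks against another rat tissue, as rat cells express these genes anyway, and could come from RNA of a species that the probes match better, such as mouse. The median change of ribosomal protein probe sets with low signal was -0.0602 on the lowest array, which met the bound against mouse RNA, yet it was 0.133 and 0.144 on the others (at most 0.0801 on the other 15), and their median level of 2.91 is near the floor of the array, where a moderate rise may not show. The median change of chromaffin genes was -0.337 at the lowest, below the other arrays but within the 0.5 set beforehand. This speaks against exchange of a whole sample for one of another cell type. Exchange among these PC12 samples could leave that median unchanged, so the median cannot judge it. Rhbg, called for AR112Q-KRKR against AR10Q responses also without the 3 arrays, read 7.24 on AR112Q-KRKR ligand array 3. Other arrays of that group read 7.57 and 7.86, and arrays of all other groups at most 5.67. This is 1 gene on 1 of the 3 arrays, and exchange among the samples was not tested further. Carry-over on the scanner or a mix of samples was not tested.

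For the lists with a higher response in AR112Q-KRKR than in AR10Q cells, the 3 arrays could contribute, since 1 lies in the AR10Q vehicle group and 1 in the AR112Q-KRKR ligand group. Without them the mean differences fell to a median ratio of 0.528 over 8 lists (range -0.0678 to 0.964), between the bounds set beforehand. With an estimated correlation between genes 0 of the 8 lists were called, so correlated members, which the preset of camera takes as nearly independent, may account for the small p-values. A difference in receptor activity through SUMO modification, which the design names, was not tested apart from these and stays open. AR112Q-KRKR and AR10Q cells also differ in tract length and in other ways between lines. This comparison cannot tell those differences from the loss of the SUMO sites.

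The line differences with vehicle may in part follow copy number. The correlation between genes 10 places apart in the rat gene order was 0.206 for AR112Q-KRKR against AR112Q cells, where the highest of 1000 shuffled orders gave 0.0416, and 0.074 for AR112Q against AR10Q cells, where it was 0.0503. A whole chromosome of 247 placed genes averaged -0.423 in the former and held 53 calls, and the difference was -0.412 with ligand. Of 156 placed genes called in that comparison, 94 lay outside the stretches that passed all shuffled orders. These were 2.03% of the genes outside, against 13.7% called inside. The stretches were chosen by the same differences that gave the calls, so a higher share inside is built in. It says nothing about the cause. For AR112Q against AR10Q cells 19 of 21 called genes lay outside. Copy number itself was not measured, and regulation shared by neighbouring genes, or an effect of the receptor form on the same genes, could give part of this and was not tested.

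Other splits of the same arrays into groups were tried for every count. For the single ligand and vehicle comparisons 10 splits are too few to judge by. The real split called 80 in AR10Q cells, where the highest other split called 2, and 40 and 189 in AR112Q and AR112Q-KRKR cells, where it called 1. In the vehicle comparisons the real split called 43 and 274 and the highest other split 1 in each; in all 5, 1 of 10 splits reached the real count, the real one itself. For the differences between responses, 100 of 100 splits reached the real count of 0 for AR112Q against AR10Q and for AR112Q-KRKR against AR112Q cells, which any split must do and which says nothing, and 3 of 100 reached the real count of 4 for AR112Q-KRKR against AR10Q cells. The highest other splits called 241, 347 and 326. Those come from the split in which all arrays of 1 line have ligand and vehicle turned, so that the difference becomes a sum of both responses, which is a structure of the samples.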

How the results depend on the processing

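The alternatives that deal with the 3 arrays that stood apart and with identical probe sets were chosen after seeing the data. Of 117 results for single genes, all kept direction and side of the threshold with distinct probe sets, with probe sets of 1 symbol and with a trended and robust prior, and 114 with probe sets at or above the median level; 106 lost their call in a fit to the compared groups only, 33 without the 3 arrays, 22 with the replicate block, 14 with the indicator, 5 with centring, 4 with quantile normalization and 3 with array weights. Of 47 list results, 41 lost their call with an estimated correlation, 28 with fry, 23 without the 3 arrays (2 more turned), 20 with the indicator (1 more turned), 18 at or above the median level, 14 with quantile normalization, 13 with array weights, 6 with centring, 5 with the compared groups only, 5 with all probe sets of a list and 2 with the replicate block. With 1 array left out at a time, 208 fits of single genes lost a call and 512 kept it, and 76 fits of lists lost a call and 290 kept it. The count for AR112Q against AR10Q responses stayed 0 under every alternative. The 1.5-fold minimum changed no count by over 1.5 times.

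Counts are given in the order AR10Q, AR112Q and AR112Q-KRKR ligand responses; shared calls in the order AR10Q with AR112Q, AR10Q with AR112Q-KRKR, AR112Q with AR112Q-KRKR, and all lines. With the replicate block the AR112Q ligand count was 19, AR112Q-KRKR against AR10Q 1, and shared calls 15 for the first pair, 15 for the last pair and 12 in all lines. Residuals of the 9 same-number pairs of a vehicle and a ligand array of 1 line correlated at -0.07 to 0.031. For the 45 same-number pairs between any groups the correlation ran from -0.28 to 0.27, with a median of -0.0012. These values show no pairing, but arrays of the same number may still have been handled together. Sets of called genes were called anew under each alternative that changes the fit. Quantile normalization gave 1 for AR112Q-KRKR against AR10Q and 0.089 (adjusted p = 0.0522) for the set called in AR10Q. Centring gave -0.052 (adjusted p = 0.148) for the set called in AR112Q-KRKR. Probe sets at or above the median level gave 178, 110 and 396, 9 for AR112Q-KRKR against AR112Q, 7 against AR10Q, 533 for AR112Q-KRKR against AR112Q with vehicle, shared calls of 61, 102, 57 and 44, and -0.011 (adjusted p = 0.39) for the set called in AR112Q-KRKR; fewer probe sets were tested there, and other causes were not examined. Probe sets with 1 symbol gave 133 and 72 in AR10Q and AR112Q, 77 shared by AR10Q and AR112Q-KRKR, and -0.025 (adjusted p = 0.331) for that set. The trended and robust prior gave 162, 106 and 344, 7 for AR112Q-KRKR against AR112Q, 65 and 453 with vehicle, shared calls of 64, 98, 65 and 52, and -0.017 (adjusted p = 0.753). Array weights, which were 0.714, 0.849 and 0.528 for the 3 arrays, gave 1 for AR112Q-KRKR against AR10Q and -0.047 (adjusted p = 0.239). A fit to the compared groups only, with fewer arrays behind each variance, gave 0, 0 and 2, 0 for AR112Q-KRKR against AR10Q, 0 and 23 with vehicle, and shared calls of 0, 0, 0 and 0. An adjusted p under 0.01 gave 42, 14 and 90, 1 for AR112Q-KRKR against AR10Q, 21 and 99 with vehicle, and shared calls of 10, 22, 11 and 8. With an estimated correlation the set differences 0.125 and -0.077 had adjusted p of 0.324 and 0.475.

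Without the 3 arrays the counts were 23 and 111 in AR112Q and AR112Q-KRKR, 1 for AR112Q-KRKR against AR112Q, 1 against AR10Q and 15 for AR112Q against AR10Q with vehicle, with 13, 13 and 10 shared by the first pair, the last pair and all lines. The set called lower in AR112Q cells turned from -0.041 to 0.43 (adjusted p = 0.0225, 9 probe sets), and the androgen response list turned to -0.019 against AR112Q and -0.012 against AR10Q cells. With the indicator the former list value was -0.017, the count for AR112Q-KRKR against AR10Q was 1, and the set called in AR10Q differed by 0.085 (adjusted p = 0.132). Except where stated, the cause was not tested. Leaving out each array in turn, the ligand counts ran from 48 (without AR10Q vehicle array 3) to 68, 12 (without AR112Q ligand array 2) to 30, and 107 (without AR112Q-KRKR vehicle array 2) to 135. The differences of responses ran from 0 to 0, 0 to 1 and 1 (without AR10Q vehicle array 1) to 3, and the vehicle counts from 21 (without AR10Q vehicle array 3) to 49 and 118 (without AR112Q-KRKR vehicle array 1) to 171. Shared calls ran from 10 to 24, 27 to 40, 9 to 25 and 8 to 17. The set differences ran from 0.059 to 0.22 and -0.19 to 0.14 for probe sets called higher and lower in AR10Q, -0.14 to -0.046 and -0.01 to 0.076 for AR112Q-KRKR, and -0.12 to 0.11 and -0.35 to 0.21 for AR112Q cells. On 68.5% of probe sets the mean was under a log2 value of 4, where a change is hard to tell from background; how far this limits the counts was not tested.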

Other observations

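Among catecholamine and chromaffin genes Th averaged 10.12 ± 0.16 (SD, 15 arrays) and Chga, a granin of secretory granules, 8.01 ± 0.18, and neither was called in a ligand comparison. Signals of different probe sets are not compared as levels of expression. Ddc read 6.92 in AR112Q and 5.54 in AR112Q-KRKR cells with vehicle. Hand2, a regulator of catecholamine genes, fell with ligand in AR10Q and AR112Q-KRKR cells (-0.77 ± 0.11 and -0.87 ± 0.11) and was -0.53 ± 0.11 in AR112Q cells (adjusted p = 0.0906). Edem1 rose in AR10Q and AR112Q-KRKR cells (0.82 ± 0.11 and 0.90 ± 0.11) and was 0.61 ± 0.11 in AR112Q cells (adjusted p = 0.0688), and Dnajb1, a co-chaperone of Hsp70, was 0.68, 0.77 and 0.64 in the 3 lines without a call in any. Other genes that rose in all 3 lines were Uxs1 (0.99, 0.89 and 0.73), the histone demethylase gene Kdm4b (0.93, 0.87 and 0.67), Ddhd1 (1.03, 0.94 and 1.04), Dip2b (1.05, 0.70 and 1.14), the actin-disassembly gene Wdr1 (0.74, 0.82 and 0.97) and the G protein gene Gna12 (0.75, 0.74 and 0.57).

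Several lists did not pass camera in any ligand comparison. Means in AR10Q, AR112Q and AR112Q-KRKR cells were -0.073, 0.0069 and -0.0033 for the SUMO pathway and -0.0032, 0.031 and 0.085 for androgen receptor coregulators (adjusted p = 0.0528 in the last). They were -0.02, -0.059 and -0.076 for catecholamine and chromaffin genes, -0.051, -0.029 and -0.089 for neurite outgrowth, and -0.091, 0.017 and 0.13 for p53 targets and apoptosis. None of the 5 lists of other cell types passed in any comparison. Their means were -0.23, -0.073 and 0.19 for fibroblasts, -0.39, -0.28 and 0.44 for Schwann cells and satellite glia, -0.17, -0.14 and 0.15 for leukocytes, 0.026, -0.069 and -0.079 for adrenal cortex, and -0.024, -0.014 and 0.058 for endothelium. Without the 3 arrays the Schwann cell and satellite glia means were -0.061, -0.04 and -0.027.

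On the 3 arrays that stood apart, 79 of the 93 raised probe sets (84.9%) averaged under a log2 value of 4 elsewhere, and 1 probe set was lower by over 2 on all 3. The number of probe sets over 2 above the mean of the other arrays was 268, 159 and 569 on these arrays and 34 to 81 on the others. Further genes read there were ND1 (10.84, 10.21 and 11.58), CYTB (10.72, 9.61 and 11.29), the caseins Csn1s1 (7.53, 5.80 and 8.40) and Csn3 (7.79, 5.61 and 7.52), B2m (9.56, 7.72 and 10.14), Vim (7.54, 7.02 and 9.51), Igfbp5 (7.88, 6.47 and 8.37), the surfactant gene Sftpc (6.91, 5.46 and 7.52) and Xist (6.64, 6.02 and 6.35 against 2.86 ± 0.29 SD). Marker lists rose by 1.18, 0.398 and 1.83 for lung, 1.46, 0.36 and 2.14 for mammary gland, 1.41, 0.807 and 2.68 for developing brain, and 0.746, 0.168 and 0.837 for fibroblasts, as medians in the order of the arrays. Ribosomal protein probe sets with high signal rose by 0.275, 0.179 and 0.252 at the median, against at most 0.15 on the other 15. The medians of the other 19 first lists rose by at most 0.769 on any array. Residuals of pairs of these arrays correlated at 0.22 to 0.44.

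A second stretch of genes differed along the chromosomes. Of the 265 genes placed on the chromosome that begins with Gdap1, 205 lay in a stretch that averaged -0.229 ± 0.25 (SD) in AR112Q-KRKR against AR112Q cells, 164 of them lower and 9 called. All 265 averaged 0.195 in AR112Q against AR10Q cells, 223 of them higher and 2 called, and -0.011 in AR112Q-KRKR against AR10Q cells. In the ligand responses the correlation between genes 10 places apart was 0.0048, -0.0033 and 0.031.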
